A study of Mus musculus with 4 samples.

How the data were processed

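Single cells from islets of NOD mice were profiled in 2 Cre control and 2 Alox15 islet knockout libraries with the 10x Genomics 3' v3 chemistry. Per the submitters' description, islets were isolated from perfused pancreata, cultured, picked by hand and dissociated with Accutase and DNase, and suspensions with over 90% viability were used. Per the submitters' processing notes, reads were processed with Cell Ranger 3.0.2 on mm10 and then with Seurat 3.1.0; the gene annotation is not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode, as the authors obtained them from Cell Ranger after its own calling of cells, for 31053 genes and 55052 barcodes. All values were whole counts, and no table of cell types by the authors was used here.

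Depth per library was 166577527, 194281870, 194000800 and 169001214 UMIs in 14531, 16602, 12328 and 11591 barcodes (Control 1, Control 2, Knockout 4, Knockout 5). Barcodes with fewer than 500 UMIs, fewer than 250 genes or over 15% mitochondrial UMIs were removed, which left 9561, 11249, 8795 and 8171. The minimum of genes removed 4371, 4735, 3138 and 2787 barcodes and the mitochondrial limit 3829, 4438, 3475 and 3333, with some failing both. Cells that passed had medians of 12568, 13375, 20499 and 14823 UMIs, 2121, 2447, 3079 and 3063 genes and 2.80%, 3.57%, 4.67% and 4.63% mitochondrial UMIs. Doublets were scored per library with Scrublet in scanpy at an assumed rate of 0.8% per 1000 barcodes, and 242, 936, 641 and 265 cells were removed (2.53%, 8.32%, 7.29% and 3.24%, against 11.6%, 13.3%, 9.86% and 9.27% assumed). Intervals of shares are exact Clopper-Pearson intervals at 95%, and the limit for a count of 0 is 3 counts; both cover counting error alone.

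Cells of all libraries were scaled to 10000 UMIs, log-transformed and clustered together without integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1.0; Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). Clusters were named from 26 marker sets. A name needed at least 3 markers found in at least 15% of cells and at least 2-fold above the median cluster. These folds were taken within each library and averaged over libraries on the log scale. Part of the naming rules, those that keep free acinar RNA from naming a cluster, was set after the clusters had been seen. Clusters with no name and clusters of doublets (at least 40% doublet calls) were left out of the comparisons but kept in the total of cells. Classes are called by the type their markers match, with "-like" where a marker set covers several types.

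Counts were summed per class and library where each library had at least 20 cells, with at least 50 for a main comparison. Knockouts were compared with controls in edgeR 4.0.16 (TMM scaling, which also holds for printed CPM of single genes, filterByExpr, robust quasi-likelihood test) under R 4.3.3, with Benjamini-Hochberg adjustment at 0.05 over all genes tested in a class. The main comparisons are beta-like, B, T or NK, dendritic and macrophage classes; the other classes and all cells together are further ones. Shares of cells were tested with edgeR on cell counts of classes with at least 10 cells in 1 library, adjusted over classes. The difference of effects between beta-like and alpha-like cells, and between macrophages and dendritic cells, was tested as an interaction, which was not among the comparisons fixed beforehand. The 39 gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01 and again with the correlation estimated. This was done where at least 5 genes of a list were tested, and members were also adjusted over the list alone. The limma fry test of a shared direction, which does not set a list against other genes, was also fixed beforehand and run. With the correlation estimated, the camera test rests on the few residual degrees of freedom that 4 libraries in 2 groups leave. It can then hardly call a list, so the lack of a call there decides nothing. Some lists lack a few genes whose symbols the matrices do not hold. Lists and the rule for naming genes were fixed before the data were examined. The rule named, among genes with an adjusted p below 0.05 and a mean log2 CPM of at least 4 and both knockout libraries on 1 side of both controls, the 10 with the largest change in each direction in a main comparison and 3 in the others, up to 10 further called members of the lists, 2 to 4 members with the smallest p of each list described, and Alox15, Cd274, Ins1 and Ins2. Pdx1 and the genes named for free RNA were chosen after their values were seen. So were Esr1, mt-Nd4l, mt-Atp8, mt-Nd3, Ifit1, Pla2g2d, Cxcl13, Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Cd3e, some of which also met the rule in a class. Gene positions and transcript lengths come from GENCODE M21 on GRCm38. Genes with near-identical copies or overlapping neighbours, such as Ins1 and Ins2, Amy1, H2-Q7 and mt-Nd4l, can share or lose reads in counting.

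The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries and no more. They give no date or batch either, so a batch that follows the groups cannot be told apart from the genotype. Esr1 sequence, a part of the Cre, followed the groups too. If the groups differ in the Cre, that difference cannot be told apart from the loss of Alox15. The share of a gene's level given by free RNA was estimated per class from 4 source classes, and genes at 50% or more were left out in an added count. On simulated changes in 200 genes, the test in beta-like cells found 83% of those of log2 1 and 96% of those of log2 2, with 6 false among 185 calls. In macrophages it found 21% and 89% (4 false among 114), and in T or NK cells 36% and 91% (7 false among 134). The simulation gave genes of like mean the same spread and held no difference between groups beyond the changed genes. Its shares therefore do not give the performance on the real libraries.

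Alternatives fixed before the data were examined were DESeq2 1.42.0, another scaling (RLE), no filter on low counts, at least 10 counts in every library, removal of the ambient list, no doublet removal, a mitochondrial limit of 10%, at least 1000 UMIs per cell, clusters at resolution 0.5, shares of immune or endocrine cells, an estimated correlation and each library left out in turn. Chosen after seeing the data were variable genes without the ambient list, free RNA genes left out, and dendritic cells with T cell receptor UMIs left out. So were macrophages without a sub-cluster that had Gpnmb among its leading genes, scaling by total UMIs alone, and acinar and ductal cells left out of the total.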

Results

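Gene expression was measured in single cells of pancreatic islets from 8-week-old nonobese diabetic (NOD) mice, a strain that develops autoimmune diabetes. A pair of libraries came from mice labelled as carrying a tamoxifen-inducible Cre recombinase under the Pdx1 promoter (Cre control, replicates 1 and 2). The other pair came from mice in which Alox15, the gene of the 12/15-lipoxygenase that oxygenates arachidonic acid, had been deleted with such a Cre in the islet (Alox15 islet knockout, replicates 4 and 5). The labels name these libraries, here called Control 1, Control 2, Knockout 4 and Knockout 5, and give no date or batch. The titles of the control libraries call them WT, without naming a Cre. The barcodes held 166577527, 194281870, 194000800 and 169001214 unique molecular identifiers (UMIs, each a captured RNA molecule) in that order. After filtering, 9319, 10313, 8154 and 7906 cells remained, 35692 in all. Of these cells, 6.36%, 5.03%, 7.09% and 9.98% carried no cell type name, a mean of 5.70% ± 0.941 (SD, n = 2) in controls and 8.53% ± 2.04 (SD, n = 2) in knockouts. The question the labels pose is what deletion of Alox15 in the islet changes in beta cells and in the immune cells around them.

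Alox15 itself (ENSMUSG00000018924, chromosome 11, 70344152 to 70352031, minus strand, GRCm38) was close to absent in both groups. Kept cells of Control 1 held 1 Alox15 UMI, those of Control 2 held 2, those of Knockout 4 held 0 and those of Knockout 5 held 7. Beta-like cells held 0, 1, 0 and 0 of these in that order, and mesenchymal-like cells 0, 1, 0 and 4. A UMI was found in 0.0107% of cells in Control 1 (exact 95% Clopper-Pearson interval 2.7e-04% to 0.0598%), in 0.0194% in Control 2 (0.00235% to 0.0700%) and in 0.0759% in Knockout 5 (0.0279% to 0.165%). The 0 of 8154 cells in Knockout 4 allows a share of cells with a UMI of up to 0.0368% by the limit of 3 counts and of 0.0452% by the exact interval; neither limits the share of cells that express the gene. The assay reads the 3' end of the RNA and the labels do not say which exons were removed, so these counts do not test the deletion. A difference in Alox15 was not detectable at this depth.

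B cells, T or natural killer (NK) cells and dendritic cells took a larger share of the knockout libraries. B cells made up 1.56% and 1.24% of cells in Controls 1 and 2 and 5.68% and 10.2% in Knockouts 4 and 5. The group means were 1.40% ± 0.223 and 7.94% ± 3.19 (SD, n = 2 each). T or NK cells went from 1.35% ± 0.781 to 7.496% ± 5.64, and conventional or migratory dendritic cell-like cells from 0.725% ± 0.326 to 2.37% ± 1.81. The edgeR test of shares gave folds of 5.67 for B cells (log2 2.50 ± 0.62, SE, adjusted p = 0.00211), 5.56 for T or NK cells (2.48 ± 0.62, adjusted p = 0.00211) and 3.27 for dendritic cells (1.71 ± 0.62, adjusted p = 0.0270). Acinar-like cells, which make digestive enzymes and do not belong to the islet, fell from 21.3% ± 11.2 to 0.758% ± 0.160 of cells (log2 -4.81 ± 0.69, adjusted p = 2.14e-06). Ductal-like cells fell from 1.56% ± 0.212 to 0.325% ± 0.113 (log2 -2.26 ± 0.64, adjusted p = 0.00541). Macrophage or monocyte-like cells took 3.19% ± 0.5998 and 3.70% ± 0.891 (log2 0.21, adjusted p = 0.850). Beta-like cells took 32.4% ± 7.75 and 41.1% ± 11.1 (log2 0.34, adjusted p = 0.850). Shares of alpha-like, delta-like, endothelial-like, mesenchymal-like, Schwann-like, neutrophil-like and plasmacytoid dendritic cell-like cells did not pass the test either, with log2 values from -0.84 for neutrophils (adjusted p = 0.411) to -0.04 for mesenchymal-like cells (adjusted p = 0.947).

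For the 3 immune classes whose share rose, the call depended on single libraries and on the total the share was taken from. Without Control 1 the log2 values and adjusted p were 2.68 (0.0935) for B cells, 3.23 (0.0595) for T or NK cells and 2.26 (0.118) for dendritic cells. Without Control 2 they were 2.35 (0.159), 1.98 (0.219) and 1.31 (0.532). Without Knockout 5 they were 2.02 (0.0739), 1.38 (0.272) and 0.59 (0.8003). The ductal call was lost without each of Control 1 (adjusted p = 0.112), Control 2 (0.122), Knockout 4 (0.123) and Knockout 5 (0.0739). With acinar and ductal cells left out of the total, a choice made after the data were seen, the values were 2.11 for B cells (adjusted p = 0.149), 2.04 for T or NK cells (0.304) and 1.295 for dendritic cells (0.304). As a share of immune cells, B cells made up 18.7%, 13.9%, 40.3% and 32.6% across the 4 libraries in order (log2 1.16, adjusted p = 0.0974). Neutrophils fell from 9.79% and 28.3% to 4.18% and 4.08% (log2 -2.20, adjusted p = 0.0110). An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so no such test was used.

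**Figure D1:**
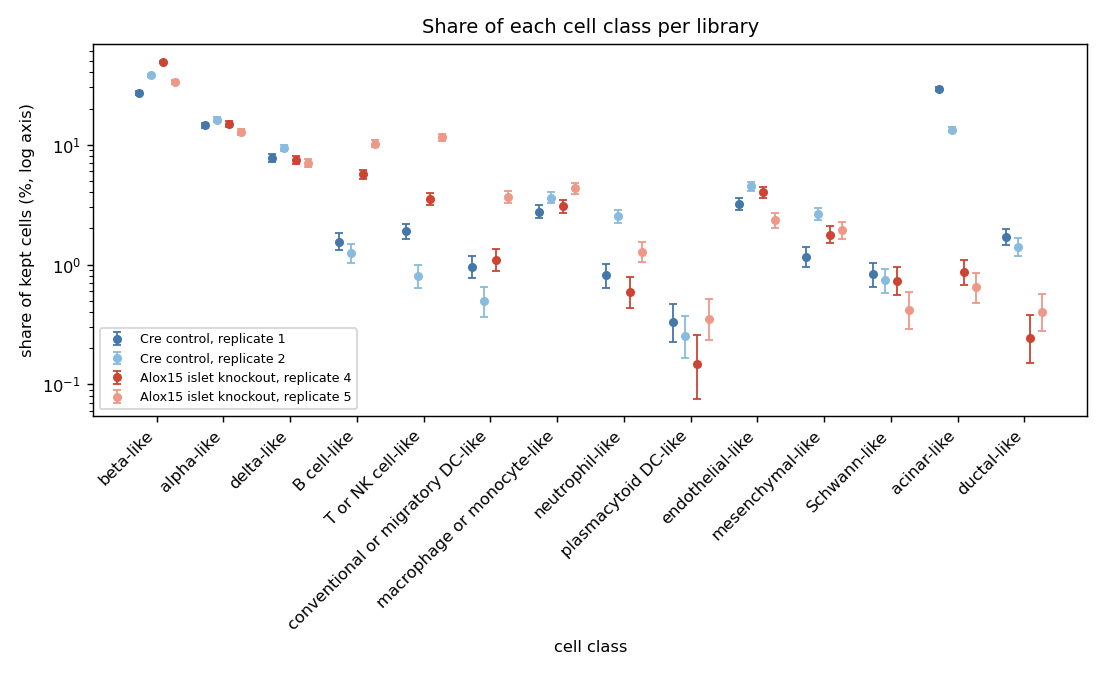
Share of kept cells (percent, log axis) in each cell class, with 1 point per library and bars for the exact 95% Clopper-Pearson interval. B cells lie at 1.56% and 1.24% in the controls and at 5.68% and 10.2% in the knockouts, while acinar-like cells lie at 29.2% and 13.4% against 0.871% and 0.645%.

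Differences that ran across cell classes came with the groups and stand beside every gene comparison. Of genes whose longest transcript is under 800 bases, the median log2 value was lower than that of longer genes in 13 of 13 classes, with differences of -0.12 in Schwann-like cells to -0.57 in acinar-like cells and -0.31 in beta-like cells. mt-Nd4l, a mitochondrially encoded subunit of respiratory complex I annotated at 297 bases, fell in 12 classes. mt-Atp8, a subunit of ATP synthase annotated at 204 bases, fell in 7. The short genes compared above were nuclear and outside the ribosomal and respiratory chain families, so that comparison does not cover mt-Nd4l or mt-Atp8. Esr1, the estrogen receptor alpha gene (ENSMUSG00000019768, chromosome 10, 4611593 to 5005614), whose ligand-binding part is built into tamoxifen-inducible Cre, rose in Schwann-like, acinar-like, delta-like, ductal-like, endothelial-like and mesenchymal-like cells, although the labels give this Cre to both groups. It did not pass the test in beta-like cells (log2 8.45, adjusted p = 0.149; 2.95 and 0.072 against 380 and 540 CPM) or in alpha-like cells (7.30, adjusted p = 0.110). In delta-like cells it stood at 1.34 and 1.31 CPM (counts scaled to a common total adjusted by TMM, as are all CPM of single genes) in the controls and at 511 and 606 CPM in the knockouts (log2 8.70, adjusted p = 2.49e-16). Transcripts of acinar cells were also present as free RNA in control droplets: summed acinar genes, scaled by total UMIs without TMM, stood at 151518 and 106531 CPM in control B cells and at 337 and 817 CPM in knockout B cells. Cells of a class also fell into different clusters by group, such as beta-like cells in clusters 0, 1 and 19 in controls and in cluster 30 (94.1%) in knockouts. B cells lay in cluster 16 in controls (95.2%) and 6 in knockouts (99.5%), T or NK cells in 7 (93.8%) and 8 (99.1%), alpha-like cells in 13 (99.6%) and 32 (96.7%), and delta-like cells in 10 (99.3%) and 11 (95.6%).

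**Figure D2:**
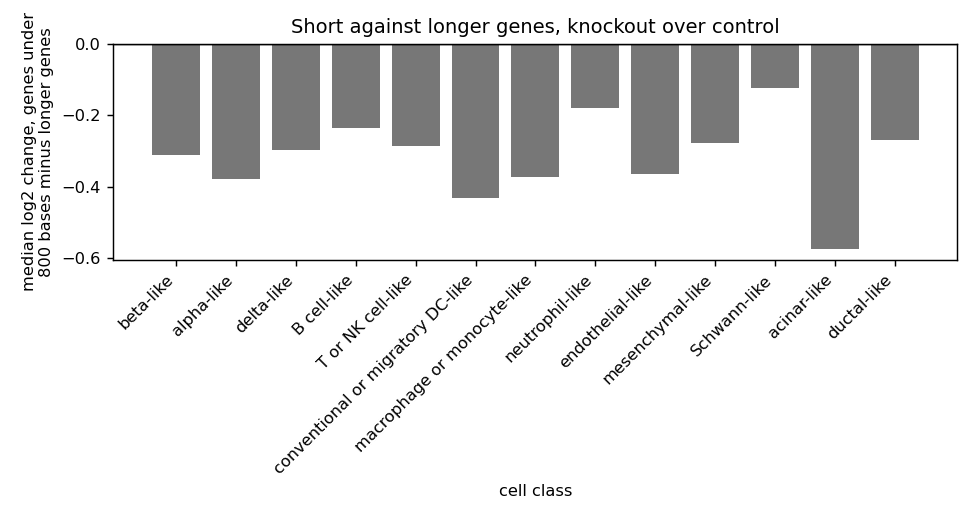
Median log2 change (knockout over control) of genes with a longest transcript under 800 bases minus that of longer genes, 1 bar per cell class. Every bar lies below 0, from -0.12 in Schwann-like cells to -0.57 in acinar-like cells.

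The comparison of beta-like cells asks what Alox15 loss changes in the insulin-producing cells. Tnfaip3 and Stat3 rose in knockout beta-like cells, and both insulin genes fell under TMM scaling. Tnfaip3 (ENSMUSG00000019850, chromosome 10, 19000910 to 19015657), which encodes the NF-kB inhibitor A20, rose 1.73-fold (log2 0.79 ± 0.07, SE, n = 2 libraries per group, adjusted p = 6.48e-04), from 16.8 and 16.04 CPM to 27.7 and 29.1 CPM. Stat3 (ENSMUSG00000004040, chromosome 11, 100885098 to 100939540), a transcription factor of cytokine signalling, rose 1.64-fold (0.71 ± 0.08, adjusted p = 0.00161). The long noncoding RNA Lncpint rose 1.94-fold (adjusted p = 1.91e-04). Klf7, a Krueppel-like transcription factor (log2 0.92), Vcl, which links adhesion sites to actin (0.83), Per1 of the circadian clock (0.69), and Arih1, Gng12, Lpin1 and Sgms1 (0.66 to 0.71) rose as well. Ins1 (chromosome 19, 52264297 to 52265476) fell by 0.40 (SE 0.11, adjusted p = 0.0427) from 218230 and 201500 CPM to 154540 and 162480 CPM. Ins2 fell by 0.42 (SE 0.12, adjusted p = 0.0482). Other genes that fell were Hspe1 and Dnajb1, a mitochondrial chaperonin and a heat shock protein (log2 -0.70 and -0.62), Gadd45g, a stress-response gene (-0.63), and Ier3, an early response gene (-0.64). Several of these changes were not particular to beta-like cells. Stat3, Klf7 and Vcl also rose in acinar-like, alpha-like and delta-like cells, and Gng12 rose in those and in ductal-like and endothelial-like cells. Hspe1 also fell in acinar-like, alpha-like, delta-like and ductal-like cells, and Gadd45g in alpha-like, delta-like and endothelial-like cells. Pdx1, the transcription factor that defines beta cells, had a log2 value of -0.03 (adjusted p = 0.846). Cd274, the gene of the T cell inhibitor PD-L1, had 1.29 (adjusted p = 0.398; 3.28, 2.14, 3.99 and 9.13 CPM).

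Insulin, the sum of Ins1 and Ins2, made up 67.5% and 65.3% of UMIs in control beta-like cells and 60.5% and 60.996% in knockout ones, so the scaling matters for these genes. Scaled by total UMIs alone, a choice made after the data were seen, neither insulin gene passed the test (log2 -0.12, adjusted p = 0.110 for Ins1, and -0.13, adjusted p = 0.0594 for Ins2). Pdx1 then stood at 0.25 (adjusted p = 0.0572), and 4795 genes were called up and 102 down, with the median gene 0.28 higher than under TMM.

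In all, 574 genes rose and 596 fell among 13891 tested in beta-like cells (edgeR, Benjamini-Hochberg adjusted p below 0.05), and DESeq2 gave 447 and 584. The edgeR total of 1170 was 340 without Control 1, 675 without Knockout 4 and 596 without Knockout 5. The insulin calls were lost without Control 1 (adjusted p = 0.064 for Ins1 and 0.0813 for Ins2), without Knockout 4 (0.319 and 0.268) and without Knockout 5 (0.231 and 0.306). The Dnajb1 call was lost without Control 1 (0.223), Control 2 (0.101) and Knockout 4 (0.0687). Without Control 1 the calls of Arih1 (0.0813) and Lpin1 (0.0557) were lost too.

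By gene list, 6 of 24 NF-kB and inflammatory cytokine targets rose in beta-like cells and none fell, with 6 up and 1 down when adjusted over the list alone. Rela, a subunit of NF-kB itself (log2 0.50), Nfkb1 (0.42) and Nfkbie (0.43) were among them. The camera test called the list up (adjusted p = 1.83e-04, adjusted p = 0.536 with an estimated correlation). Of 25 type I interferon response genes 5 rose, and 11 were up and 1 down adjusted over the list alone (camera adjusted p = 5.98e-11, adjusted p = 0.536 with an estimated correlation). Among them were Ifit1, which blocks viral translation (log2 1.18, 1.77 and 1.88 against 3.47 and 4.83 CPM), the RNA sensor Ifih1 (0.67) and Stat2 (0.49). The Ifit1 call was lost without Control 1 (adjusted p = 0.103) and without Control 2 (0.0577). Of 20 genes of MHC class I presentation 3 rose (5 adjusted over the list alone, camera adjusted p = 9.84e-11, adjusted p = 0.536 with an estimated correlation). These were the peptide trimming enzyme Erap1 (log2 0.50), the loading factor Tapbp (0.52) and the chaperone Calr (0.41). The ER stress and unfolded protein response list had 6 of 29 genes up (8 adjusted over the list alone), such as Hyou1 (0.34) and Trib3 (0.40), with a camera adjusted p = 0.00483 and an adjusted p = 0.554 with an estimated correlation. That camera call was lost without Control 2 (adjusted p = 0.0578) and without Knockout 4 (0.243).

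Of 33 nuclear genes of oxidative phosphorylation 7 fell (14 adjusted over the list alone, camera adjusted p = 4.94e-04, adjusted p = 0.536 with an estimated correlation). Among them were Cox6c, Cox5b and Ndufa4, subunits of the respiratory chain (log2 -0.36, -0.36 and -0.34). This list moved together with the lower values of short transcripts, and its call was lost when scaled by total UMIs alone (median 0.10, adjusted p = 0.245). Among 28 immediate early and dissociation genes 5 fell and 2 rose (6 and 2 adjusted over the list alone, camera adjusted p = 4.94e-04, adjusted p = 0.592 with an estimated correlation). Of 26 beta cell identity genes, 3 fell (3 adjusted over the list alone), Ins1, Ins2 and the transcription factor Insm1 (log2 -0.28), and the camera test did not call the list (adjusted p = 0.485). Of 13 mitochondrially encoded genes, 3 rose and 4 fell (4 and 4 adjusted over the list alone), mt-Nd2 at 0.59 and mt-Nd5 at -0.56. A rise of mt-Nd2 was also called in alpha-like, delta-like and T or NK cells. The median of the list in beta-like cells was 0.11, while the mean was -0.18 and camera called the list down (adjusted p = 0.0386, adjusted p = 0.671 with an estimated correlation). The call of the list was lost without Control 2 (adjusted p = 0.256), without Knockout 5 (0.27) and when scaled by total UMIs alone (0.0935), and the mt-Nd5 call without Knockout 5 (0.0554).

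In knockout B cells the interferon-induced genes Zbp1 and Ifi27l2a rose, and genes such as Cxcr4 and Notch2 fell. Zbp1, a sensor of Z-form nucleic acids (ENSMUSG00000027514, chromosome 2, 173206612 to 173218923), rose by log2 1.69 (adjusted p = 0.0166; 41.2 and 20.2 against 88.3 and 111 CPM). Ifi27l2a, an interferon-induced gene of the inner mitochondrial membrane, rose by 1.04 (adjusted p = 0.00558; 572 and 501 against 1097 and 1113 CPM). These were the 2 genes that rose among 7152 tested (edgeR), while 62 fell. Most of those that fell are genes of acinar cells, such as Tff2, Cuzd1, Spink1 and Ctrc, which moved with the free acinar RNA given above. Without the genes for which free RNA gives at least 50% of the level, a choice made after the data were seen, 11 fell. Among these were Cxcr4, the receptor for the homing chemokine CXCL12 (log2 -1.302, adjusted p = 0.0049; 254.5 and 225 against 81.8 and 111 CPM), Notch2, a receptor needed for marginal zone B cells (-1.25, adjusted p = 0.0124), and Trp53inp1 and Tob1, genes of cell cycle arrest (-1.99 and -1.70). Of 15 type I interferon response genes 2 rose and none fell (5 up adjusted over the list alone, camera adjusted p = 7.99e-04, adjusted p = 0.877 with an estimated correlation). Of 37 genes of the list of ambient islet and acinar RNA, 14 fell (23 down and 1 up adjusted over the list alone).

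The total of 64 genes in B cells was 206 without Control 1, 10 when clusters were built without the ambient list and 129 when scaled by total UMIs alone (73 up and 56 down). The Ctrc call was lost without Control 1 (adjusted p = 0.317) and without Control 2 (0.505), the Zbp1 call without Control 2 (log2 1.29, adjusted p = 0.0604) and the Cxcr4 call without Knockout 4 (-1.11, adjusted p = 0.0554).

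In T or NK cells, the cell cycle genes Mki67 and Top2a rose in the knockouts and the NK receptor genes Klrk1 and Ncr1 fell. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), a marker of dividing cells, rose by log2 1.62 (adjusted p = 0.0222; 40.9 and 45.2 against 164 and 101 CPM). Top2a, a topoisomerase of DNA replication, rose by 1.28 (adjusted p = 0.0207). Uhrf1, which maintains DNA methylation (log2 1.99), the linker histone gene Hist1h1b (2.19), the chemokine gene Ccl3 (2.51) and Ikzf4, a transcription factor of regulatory T cells (2.50), rose as well. Klrk1, the gene of the activating receptor NKG2D (ENSMUSG00000030149, chromosome 6, 129610323 to 129623864), fell by 1.79 (adjusted p = 6.10e-04; 156 and 126 against 41.3 and 42.2 CPM). Ncr1, the gene of the NK receptor NKp46, fell by 2.25 (adjusted p = 0.00371; 62.4 and 85.3 against 20.4 and 11.6 CPM). Ccl5 (log2 -1.28, a transcript of 668 bases), Klrd1 (-1.27), Ccl1 (-3.23) and Klf2, a transcription factor of resting and recirculating T cells (-1.51), fell too. The NK or type 1 innate lymphoid-like sub-cluster made up 12.99% and 18.3% of the class in the controls and 5.24% and 3.96% in the knockouts. A sub-cluster led by acinar transcripts made up 77.4% and 36.6% in the controls and 0.350% and 0.661% in the knockouts.

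Of 7536 genes tested in T or NK cells, 24 rose and 70 fell (edgeR), and 58 fell without genes of free RNA. With scaling by total UMIs alone, 38 were called up and 50 down. Of 27 cell cycle genes 2 rose and none fell (12 up adjusted over the list alone, camera adjusted p = 3.94e-14, adjusted p = 0.929 with an estimated correlation). Of 26 T and NK effector genes 6 fell and 1 rose (9 and 1 adjusted over the list alone), Klrk1, Ccl5 and Klrd1 among those that fell and Ccl3 the one that rose (camera adjusted p = 1.01e-08, adjusted p = 0.929 with an estimated correlation). The total of 94 genes was 188 without Control 1, 55 without Knockout 4 and 146 without Knockout 5. The Mki67 call was lost without Control 1 (adjusted p = 0.214), Control 2 (0.0565) and Knockout 4 (0.105), the Top2a call without Control 1 (0.0531) and Knockout 4 (0.153), and the Uhrf1 call without Control 1 (0.0742), Control 2 (0.095) and Knockout 4 (0.0661). The calls of Ccl5 (0.0752) and Hist1h1b (0.42) were lost without Control 1, and those of Ccl3 (0.0874 and 0.122) and Ikzf4 (0.0874 and 0.052) without Control 2 and without Knockout 5.

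In conventional or migratory dendritic cell-like cells, the uptake receptor gene Fcgr1 and chemokine genes such as Ccl17 fell in the knockouts, and genes of T cells rose. Fcgr1, the high-affinity receptor for IgG (ENSMUSG00000015947, chromosome 3, 96282909 to 96293969), fell by log2 2.96 (adjusted p = 4.20e-04; 164 and 94.4 against 14.5 and 18.1 CPM). The chemokine genes Ccl17, Ccl6 and Ccl9 fell by 3.91, 3.29 and 3.09, with Ccl17 (a transcript of 514 bases) at 202 and 428 against 12.3 and 24.6 CPM (adjusted p = 0.0304). H2-DMb1 and H2-DMa, the chaperone that loads peptides onto MHC class II, fell by 0.91 (adjusted p = 0.0142) and 0.71 (adjusted p = 0.0360). The T cell genes that rose included Cd3e of the T cell receptor complex (log2 3.16, adjusted p = 0.0288; 10.7 and 2.78 against 44.6 and 83.8 CPM), Cd28 (3.46) and Thy1 (3.96). Xcl1, the ligand of XCR1 on cross-presenting dendritic cells, was at 0 in both controls and at 205 and 114 CPM in the knockouts, and Tcf7, a T cell transcription factor, at 0 and at 34.6 and 25.7 CPM. Cells with a UMI of the T cell receptor complex made up 3.37% and 1.96% of the class in the controls and 8.99% and 17.0% in the knockouts. The class was led by an unnamed sub-cluster with Ccr7, Ccl22 and Xcr1 in the controls (83.1% and 76.5%) and by a pair of migratory dendritic cell-like sub-clusters in the knockouts (34.8% and 43.9%, 43.8% and 36.7%).

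Of 5925 genes tested in dendritic cells, 29 rose and 103 fell (edgeR). The balance depended on the scaling: by total UMIs alone, 69 were called up and 65 down. Of 10 genes of phagocytosis and complement 4 fell and none rose (7 down adjusted over the list alone), with Fcgr2b at -2.83 and Fcer1g at -1.42 (camera adjusted p = 5.41e-08, adjusted p = 0.473 with an estimated correlation). Of 18 genes of chemokines and their receptors 6 fell (9 down and 1 up adjusted over the list alone, camera adjusted p = 3.60e-07, adjusted p = 0.494 with an estimated correlation). Of 11 MHC class II genes 2 fell (6 adjusted over the list alone, camera adjusted p = 0.00559, adjusted p = 0.637 with an estimated correlation). Of 20 genes of T cell receptor signalling 3 rose (7 up and 3 down adjusted over the list alone, camera adjusted p = 9.20e-04, adjusted p = 0.637 with an estimated correlation). The total of 132 genes was 503 without Control 1, 539 without Control 2, 46 without Knockout 4, 32 without Knockout 5 and 74 without cells holding a T cell receptor UMI. The calls of Ccl17 (adjusted p = 0.0774 and 0.0718), H2-DMb1 (0.309 and 0.582), Cd28 (0.316 and 0.753) and Tcf7 (0.15 and 0.17) were lost without Knockout 4 and without Knockout 5, and those of Fcgr1 (0.0686), Ccl6 (0.207), Ccl9 (0.0794), Thy1 (0.333) and Cd3e (0.301) without Knockout 5. That of the MHC class II list was lost without Control 1 (0.135) and Knockout 4 (0.0705).

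In macrophage or monocyte-like cells a single gene rose. Pla2g2d, the gene of a secreted phospholipase A2 (ENSMUSG00000041202, chromosome 4, 138775735 to 138782046), rose 19.0-fold (log2 4.25 ± 0.44, SE, adjusted p = 0.0368), from 11.9 and 3.67 CPM to 144 and 138 CPM. A pair of sub-clusters with Apoe, C1qa and Tmem119 differed by group: the first held 44.2% and 41.6% of the class in the controls and 0.400% and 0.292% in the knockouts, the second 0% and 3.22% against 50.4% and 48.2%. Pla2g2d also led a macrophage-like sub-cluster with Cxcl13 that held 3 and 0 cells in the controls and 22 and 56 in the knockouts. Of 9363 genes tested 20 fell (edgeR), and 3 fell without genes of free RNA; these included mt-Nd4l (log2 -1.63, adjusted p = 0.0323) and Rgcc, a regulator of the cell cycle (-1.54, adjusted p = 0.0394). At an unadjusted p below 0.05 there were 768 genes, and DESeq2 called 11 up and 50 down.

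No gene of the MHC class II list passed the test over all genes in macrophages (0 of 10), and 8 were up when adjusted over the list alone, with values of 1.21 for H2-DMb2 (adjusted p = 0.104) and 0.997 for H2-Aa (0.348). The camera test called the list up (adjusted p = 6.41e-09, adjusted p = 0.665 with an estimated correlation). The interferon-gamma response list gave 0 of 23 over all genes and 11 up adjusted over the list alone, with Irgm1 and Gbp7, genes of the immunity-related GTPases and the guanylate-binding proteins, at 1.09 and 1.08 (camera adjusted p = 7.23e-16, adjusted p = 0.665 with an estimated correlation). MHC class I presentation gave 0 of 20 and 9 up adjusted over the list alone, Tap1 at 1.23 and Psmb8 at 0.78 (camera adjusted p = 2.63e-10, adjusted p = 0.665 with an estimated correlation). The list of classically activated macrophages had a median of 0.98 and 6 of 20 up adjusted over the list alone (camera adjusted p = 6.41e-09, adjusted p = 0.665 with an estimated correlation). That of alternatively activated and resident macrophages had a median of -0.58 with 1 up and 3 down of 28 adjusted over the list alone (camera adjusted p = 2.58e-05, adjusted p = 0.665 with an estimated correlation). The total of 21 genes was 205 without Control 1, 72 without Control 2, 13 without Knockout 4, 6 without Knockout 5 and 0 when the ambient list was removed. The calls of Pla2g2d (adjusted p = 0.139 and 0.19), mt-Nd4l (0.193 and 0.368) and Rgcc (0.164 and 0.408) were lost without Knockout 4 and without Knockout 5.

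Some interferon-induced genes also rose in endothelial-like, alpha-like and delta-like cells, while in mesenchymal-like cells the type I interferon list had a median of -0.15 and none of its 30 genes passed the test. In endothelial-like cells Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731) rose 4.19-fold (log2 2.07 ± 0.18, SE, adjusted p = 1.10e-04; 21.8 and 24.3 against 105 and 89.8 CPM). Zbp1 rose 7.42-fold (adjusted p = 0.00328), and Irf7, a master regulator of interferon genes, rose by log2 1.22. The antigen presentation genes H2-K1 (0.74), B2m (0.68) and Psmb8 (0.78) rose there as well. Of 25 type I interferon response genes 9 rose in endothelial-like cells (19 adjusted over the list alone, camera adjusted p = 2.48e-32, adjusted p = 0.189 with an estimated correlation). Of 20 MHC class I genes 8 rose (15 adjusted over the list alone, camera adjusted p = 5.46e-16, adjusted p = 0.792 with an estimated correlation). In alpha-like cells 14 of 20 type I interferon response genes rose (18 adjusted over the list alone, camera adjusted p = 8.40e-27, adjusted p = 0.745 with an estimated correlation). Ifitm3 (0.98) and Xaf1 (1.13) were among them, and Ifi27 rose by 1.03 (adjusted p = 4.24e-05). Fos, an immediate early gene, fell by 1.301 in alpha-like cells (adjusted p = 4.19e-04; 956 and 1021 against 345 and 458 CPM). In delta-like cells 12 of 23 type I interferon response genes rose (20 adjusted over the list alone, camera adjusted p = 5.69e-45, adjusted p = 0.651 with an estimated correlation), Ifit1 by 1.94 and Isg15 by 2.14.

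Counts up and down were 418 and 463 of 12540 genes in alpha-like cells, 91 and 150 of 11920 in delta-like cells, 26 and 20 of 9083 in endothelial-like cells, 305 and 484 of 11186 in acinar-like cells and 50 and 17 of 8602 in ductal-like cells. They were 1 and 1 of 10518 in mesenchymal-like cells (Esr1 up and Lcn2, the gene of lipocalin 2, which fell by 4.09, adjusted p = 0.00269), 9 and 32 of 1909 in neutrophil-like cells and 3 and 14 of 5766 in Schwann-like cells. DESeq2 called fewer in alpha-like (99 up and 237 down), delta-like (27 and 90) and acinar-like cells (266 and 372). It called 25 and 45 in endothelial-like, 52 and 33 in ductal-like and 8 and 26 in mesenchymal-like cells. In neutrophil-like cells it called 10 and 32, and in Schwann-like cells 4 and 13. The balance of up and down depended on the scaling. By total UMIs alone the counts up and down were 692 and 146 in alpha-like, 245 and 55 in delta-like, 48 and 8 in endothelial-like, 6116 and 88 in acinar-like, 130 and 51 in ductal-like, 19 and 32 in neutrophil-like and 17 and 20 in Schwann-like cells. The acinar total of 789 was 324 without Knockout 4, 428 without Knockout 5 and 6204 when scaled by total UMIs alone, and the ductal total of 67 was 253 without Control 1, 204 without Control 2 and 206 without Knockout 4. The mesenchymal total of 2 was 16 without Control 1, 5 without Control 2 and 41 without Knockout 4. The neutrophil total of 41 was 87 without Knockout 4 and 66 without Knockout 5, and the Schwann total of 17 was 8 without Control 2, 217 without Knockout 4 and 46 without Knockout 5. The alpha total of 881 was 580 without Control 1, 1478 without Control 2, 157 without Knockout 4 and 15 without Knockout 5. The delta total of 241 was 130 without Control 1, 134 without Knockout 4 and 62 without Knockout 5. The endothelial total of 46 was 189 without Control 2, 130 without Knockout 4 and 107 without Knockout 5. The Zbp1 call was lost there without Control 2 (adjusted p = 0.057). The Fos call in alpha-like cells was lost without each of Control 1 (adjusted p = 0.145), Control 2 (0.0592), Knockout 4 (0.0635) and Knockout 5 (0.0608).

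**Figure D3:**
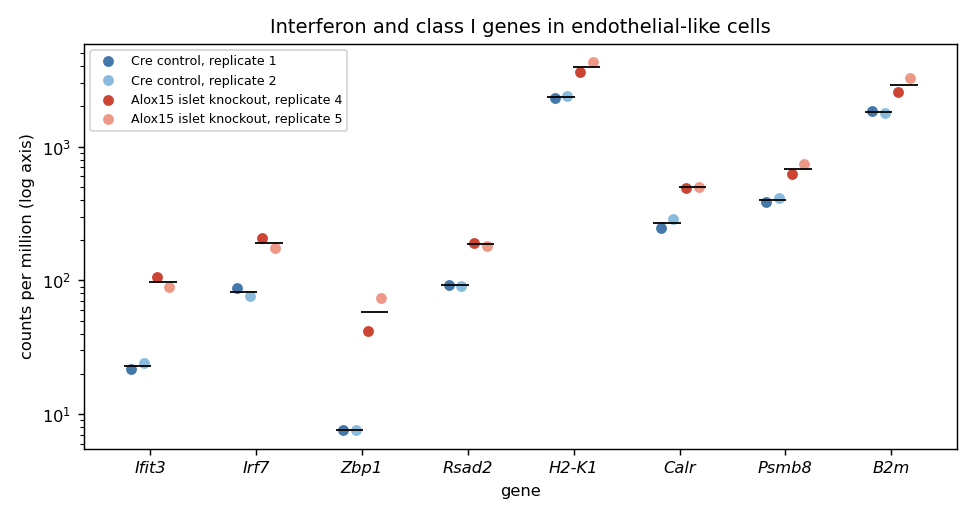
Scaled counts (CPM, log axis) of 8 interferon-induced and antigen presentation genes in endothelial-like cells, 1 point per library and a black line for each group mean. Ifit3 lies at 21.8 and 24.3 in the controls and at 105 and 89.8 in the knockouts.

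**Figure D4:**
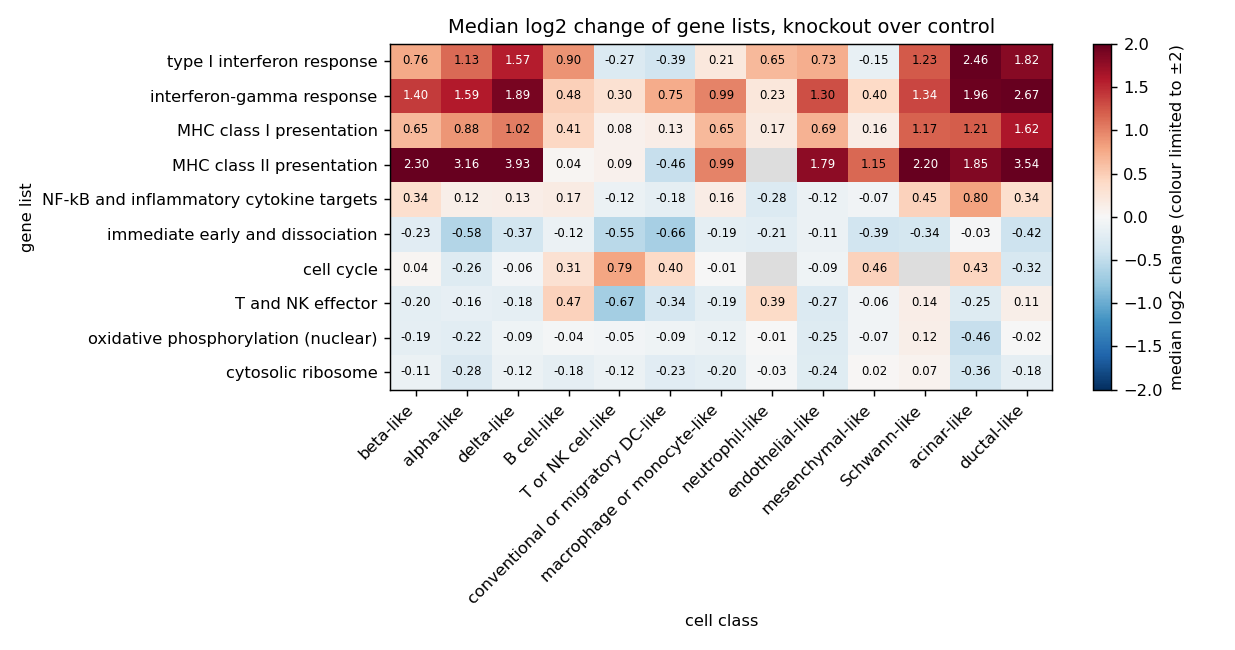
Median log2 change (knockout over control) of 10 gene lists in 13 cell classes, with colours limited to -2 and 2. The type I interferon list has its highest median in acinar-like cells (2.46) and its lowest in dendritic cells (-0.39).

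Genes close to Alox15 were tested apart, since a congenic segment can differ between strains. Within 20 Mb of the gene, 45 of 480 genes (9.38%) had changed in beta-like cells against 1125 of 13397 (8.40%) elsewhere (Fisher's exact test, two-sided, adjusted p = 0.752). The counts were 1 of 236 in B cells (0.906), 5 of 270 in T or NK cells (0.752), 7 of 214 in dendritic cells (0.752) and 0 of 336 in macrophages (1). The test compares shares and cannot say whether a single gene changed with a carried segment. In beta-like cells Elobl, at 18.6 Mb from Alox15, had a log2 value of -9.59 (edgeR adjusted p = 1.91e-04). Of genes named above, Per1 lies at -1.25 Mb and Tcf7 at -18.1 Mb. Ccl1 lies at 11.9 Mb, and Ccl3, Ccl5, Ccl6 and Ccl9 lie at 13.2 to 13.3 Mb.

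Over all cells of a library together, 1 of 17121 genes fell and none rose (edgeR), with 3298 genes at an unadjusted p below 0.05 and 467 up and 677 down by DESeq2. Without Control 1 the total was 40, without Control 2 it was 101, and without Knockout 4 and without Knockout 5 it was 0. Scaled by total UMIs alone, 3743 genes were called up and 333 down.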

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

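All tests of Esr1, that of the long respiratory chain genes, that of an even shift over classes and the tests of a difference between classes were chosen only after the results were seen; those of short transcripts and of leukocyte RNA were set before.

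The change (knockout over control) of 11 of 14440 genes differed between beta-like and alpha-like cells (edgeR interaction, Benjamini-Hochberg), 6 larger in beta-like and 5 larger in alpha-like cells, with 877 at an unadjusted p below 0.05. Fos, an immediate early gene, had a change 0.96 higher in beta-like than in alpha-like cells (log2; adjusted p = 0.0341). Between macrophages and dendritic cells the change of 56 of 10080 genes differed, 52 of them larger in macrophages, with 844 at an unadjusted p below 0.05. For MHC class II genes the log2 change from control to knockout, not the level, was higher in macrophages than in dendritic cells, by 1.49 (H2-Aa), 1.56 (H2-Eb1), 1.53 (H2-Ab1), 1.32 (Cd74), 1.57 (H2-DMa) and 1.76 (H2-DMb1). The change was also higher in macrophages for the receptors Fcgr1 (3.34) and Cysltr1 (2.85), the heme oxygenase gene Hmox1 (3.18), the transcription regulator Id3 (2.38) and the chemokine genes Ccl6 (2.47) and Ccl17 (3.90). For the MHC class II list as a whole the median difference between the changes was 1.49 (camera adjusted p = 2.64e-12; adjusted p = 0.607 with an estimated correlation).

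Part of the type I interferon list rose in knockout beta-like (5 of 25 genes), alpha-like (14 of 20), delta-like (12 of 23) and endothelial-like cells (9 of 25), and of 20 MHC class I genes 3, 2, 3 and 8 rose. By camera with an estimated correlation none of these lists was called (lowest adjusted p = 0.189). With so few libraries that version can hardly call a list, so this decides nothing. The fry test of direction called 0 lists in alpha-like, delta-like and endothelial-like cells and 2 of 36 in beta-like cells. RNA of immune cells, which were more frequent in the knockouts, gave 1.86% of the summed rise of the type I interferon list in beta-like cells, which argues against it as the source, while for MHC class II, where 1 of 8 genes passed (camera adjusted p = 2.52e-07; adjusted p = 0.536 with an estimated correlation), it gave 35.4% of the summed difference, which leaves free or doublet RNA undecided. A shift of library processing alike in every class is argued against by list medians that lie 2.84 apart on the log2 scale, from 2.46 in acinar-like cells to -0.39 in dendritic cells. A response of islet cells to more immune cells, or to the loss of Alox15, may remain among the explanations. So may a batch that follows the groups, since the labels give none. These were not tested, and the higher immune shares, whose calls depended on single libraries and on the total, do not establish a larger infiltrate.

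Transcripts annotated as short were lower in the knockouts in nearly every class, mt-Nd4l and mt-Atp8 among them. The test of length below used nuclear genes outside the ribosomal and respiratory chain families, so it does not say whether length set the fall of mt-Nd4l and mt-Atp8. Lower recovery of short transcripts, whatever their function, needed genes under 800 bases to lie at least 0.05 below longer genes, and this was so in 13 of 13 classes. Lower expression of the respiratory chain as a pathway is left undecided: its genes over 1500 bases had medians of -0.082 in beta-like and -0.11 in alpha-like cells, with 11 and 9 of 17 below 0. Transcripts such as mt-Nd3, at 348 bases, rose in beta-like cells (log2 0.36; adjusted p = 0.0333), so length is not the whole account. A difference in library preparation may therefore underlie part of the lower values of small ribosomal and respiratory genes, and genotype was not tested apart from it.

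Esr1 RNA was found in the knockout libraries and almost none in the controls, although the genotype labels give an inducible Cre, which contains Esr1 sequence, to the controls as well. The titles of the control libraries call them WT, which leaves open whether they carry a Cre. In beta-like cells the mean level was 390 times as high in the knockouts (edgeR adjusted p = 0.149), which argues against a transgene expressed alike in both groups. Free RNA of beta-like cells, scaled by the insulin share, left Esr1 at least 3.71 times too high in alpha-like and endothelial-like cells. In mesenchymal-like cells the lower of the ratios was 2.68 (7.84 in the other library). The test was first written for these classes together, and the value of 2.68 did not pass its bound, so it was undecided. The classes were parted, with the same bound, only after the ratios were seen. Parted so, alpha-like and endothelial-like cells passed the bound and mesenchymal-like cells did not. In immune cells the higher ratio was 1.90, which was undecided too. Controls without a Cre, a different Cre construct, a different age of its induction or a different strain background may explain the gap, and none was tested. If the controls lack the Cre, every comparison of the groups is also one of Cre presence.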

How the results depend on the processing

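The choice of variable genes without the ambient list, free RNA genes left out and T cell receptor UMIs left out were chosen only after the data were seen. So were the macrophage sub-cluster with Gpnmb left out, scaling by total UMIs alone, and acinar and ductal cells left out of the total. The other alternatives were fixed before. No paired analysis was possible because the replicate numbers of the groups are not shared. Leaving out a library leaves a group with 1 library, which is then assumed to vary like the other group. Scaling by DESeq2 size factors (RLE) moved no class median by over 0.02. Scaling by total UMIs alone moved it up by 0.060 (ductal) to 1.08 (acinar), with 0.28 in beta-like cells. Of 157 called named genes 63 kept direction and call under every alternative run and 90 under every library left out; of 142 called lists 81 kept theirs under every library left out and 0 with an estimated correlation. With so few libraries the camera test with an estimated correlation can hardly call a list, so its lack of calls decides nothing. Where no reason is given, the cause was not tested.

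Gene counts changed as follows. With the DESeq2 test there were 1144 (all cells), 336 (alpha), 117 (delta), 70 (endothelial), 61 (macrophage) and 34 (mesenchymal). With the ambient list removed there were 8 (Schwann), 0 (macrophage; 21 by edgeR with it, 61 by DESeq2) and 19 (neutrophil). With at least 10 counts in every library, which tests fewer genes, there were 40 (B cells), 8 (Schwann), 165 (T or NK), 65 (dendritic), 78 (endothelial), 10 (macrophage), 1 (mesenchymal) and 15 (neutrophil). With no filter on low counts there were 179 (B cells), 78 (Schwann), 207 (T or NK), 2 (all cells), 1641 (alpha), 2275 (beta), 372 (dendritic), 669 (delta), 290 (ductal), 251 (endothelial), 342 (macrophage), 276 (mesenchymal) and 64 (neutrophil). With at least 1000 UMIs per cell there were 8 (B cells), 62 (T or NK), 102 (acinar), 1441 (alpha), 779 (beta), 62 (dendritic) and 1 (neutrophil). At resolution 0.5 there were 7 (B cells), 52 (T or NK) and 1824 (delta). With a mitochondrial limit of 10% there were 12 (B cells), 33 (Schwann), 301 (acinar), 1436 (alpha) and 87 (endothelial). With no doublet removal there were 121 (ductal), 24 (endothelial) and 42 (macrophage), and Alox15 had 16 UMIs in Knockout 5. With free RNA genes left out, by construction, there were 13 (B cells), 3 (Schwann), 4 (macrophage) and 12 (neutrophil). With variable genes without the ambient list there were 10 (B cells), 417 (acinar), 44 (alpha), 540 (delta) and 80 (endothelial); no dendritic class existed there, and most knockout alpha-like cells lost their name (share log2 -5.35). Scaled by total UMIs alone there were 129 (B cells), 37 (Schwann), 6204 (acinar), 4897 (beta), 181 (ductal) and 4076 (all cells), and counts that stayed near their size changed their balance of up and down: 692 and 146 (alpha), 245 and 55 (delta), 48 and 8 (endothelial), 69 and 65 (dendritic) and 38 and 50 (T or NK). The insulin calls in beta-like cells (log2 -0.12 and -0.13) and the Ccl17 call in dendritic cells (-3.68, adjusted p = 0.0522) were lost there. There were 74 dendritic genes without cells with T cell receptor UMIs and 10 macrophage genes without the sub-cluster with Gpnmb.

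With an estimated correlation 0 lists were called in every class, against 5 (B cells), 14 (Schwann), 6 (T or NK), 16 (acinar), 9 (alpha), 19 (beta), 14 (dendritic), 9 (delta), 13 (ductal), 11 (endothelial), 12 (macrophage), 11 (mesenchymal) and 3 (neutrophil) by camera at the preset correlation. Scaled by total UMIs alone 12 were called in beta-like cells. The fry test of direction called 2 (B cells), 10 (acinar), 2 (beta), 2 (dendritic) and 1 (neutrophil). It called 0 in Schwann-like, T or NK, alpha-like, delta-like, ductal-like, endothelial-like, macrophage and mesenchymal-like cells. Without regard to direction, fry called 4 (B cells), 10 (T or NK), 27 (acinar), 4 (alpha), 15 (beta), 19 (dendritic), 1 (delta), 3 (endothelial) and 4 (neutrophil). Shares of cells changed their call or sign in these cases. With acinar and ductal cells left out of the total, log2 was 2.11 (B cells), 2.04 (T or NK), 1.295 (dendritic), -0.0072 (beta) and -0.14 (macrophage). As a share of immune cells it was 1.16 (B cells), 0.96 (T or NK), 0.20 (dendritic), -1.05 (macrophage) and -2.20 (neutrophil). At resolution 0.5 it was 2.52 (T or NK), 1.76 (dendritic) and 0.35 (delta), and with no doublet removal 1.71 (dendritic).

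Leaving out each library in turn gave these lowest and highest gene counts: 66 and 206 (B cells), 8 and 217 (Schwann), 55 and 188 (T or NK), 324 and 634 (acinar), 0 and 101 (all cells), 15 and 1478 (alpha), 340 and 1365 (beta), 32 and 539 (dendritic), 62 and 355 (delta), 49 and 253 (ductal), 58 and 189 (endothelial), 6 and 205 (macrophage), 2 and 41 (mesenchymal) and 56 and 87 (neutrophil). Lists called ranged from 4 to 13 (B cells), 5 to 10 (T or NK), 8 to 16 (alpha), 11 to 22 (beta), 8 to 21 (mesenchymal) and 2 to 5 (neutrophil). Shares ranged over log2 2.02 to 2.87 (B cells), 1.38 to 3.23 (T or NK), 0.59 to 2.33 (dendritic), -2.66 to -1.94 (ductal), -0.71 to 0.059 (endothelial), -0.059 to 0.44 (macrophage), -0.52 to 0.68 (mesenchymal), -1.50 to 0.19 (neutrophil) and -0.98 to 0.28 (plasmacytoid).

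Lists turned direction in the camera test, which ranks a list against the other genes and can turn while the median keeps its sign, when a library was left out. The medians ranged as follows: NF-kB targets 0.15 to 0.62 in Schwann-like and -0.41 to 0.57 in ductal-like cells, glycolysis and hypoxia -0.047 to 0.83 in Schwann-like cells, secretory granule -1.49 to 0.40 in T or NK cells, T and NK effector -0.24 to 0.36 in beta-like cells, beta cell identity -1.32 to 0.22 in endothelial-like cells, type I interferon -0.040 to 0.48 in macrophages, and, in mesenchymal-like cells, cell cycle 0.0052 to 2.01 and resident macrophage -1.09 to 0.12. Scaled by total UMIs alone, 4 lists turned direction in acinar-like cells, with medians of 0.72 (ER stress), 0.63 (oxidative phosphorylation), 0.92 (mitochondrially encoded) and 0.73 (cytosolic ribosome).

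Of single genes, Ins1, Ins2 and Cd274 turned sign when a library was left out. Ins1 ranged over -0.85 to 0.84 (B cells), -0.43 to 0.46 (T or NK), -0.029 to 0.87 (alpha), -0.073 to 0.37 (dendritic), -1.62 to 0.44 (delta), -0.88 to 1.81 (ductal) and -1.23 to 0.98 (mesenchymal). Ins2 ranged over -0.73 to 1.10 (B cells), -0.46 to 0.27 (T or NK), -0.34 to 0.28 (dendritic), -1.66 to 0.19 (delta), -0.95 to 1.63 (ductal) and -1.31 to 0.87 (mesenchymal), and Cd274 over -1.17 to 0.29 (B cells), -0.067 to 1.28 (alpha) and -0.12 to 0.39 (neutrophil). With a mitochondrial limit of 10%, Ins1 was at -0.50 (T or NK), -1.73 (alpha), 0.19 (ductal) and 0.30 (macrophage) and Ins2 at -1.68 (alpha), 0.062 (ductal) and 0.27 (macrophage). With at least 1000 UMIs per cell, Ins1 was at -0.49 (T or NK), 0.34 (acinar), -1.45 (alpha) and 0.035 (macrophage) and Ins2 at 0.29 (acinar), -1.36 (alpha) and 0.012 (dendritic). At resolution 0.5, Ins1 was at -0.55 (T or NK), -0.56 (alpha) and 3.54 (delta) and Ins2 at -0.50 (alpha) and 3.33 (delta). With no filter on low counts Ins2 was at 0.032 (T or NK) and 0.019 (dendritic), with at least 10 counts in every library at 0.0029 and 0.064, and without T cell receptor UMIs at 0.11 (dendritic). Scaled by total UMIs alone, Ins1 was at 0.70 (acinar) and 0.0900 (ductal) and Ins2 at 0.042 (T or NK), 0.66 (acinar) and 0.21 (dendritic). With no doublet removal Ins1 and Ins2 were at -0.33 and -0.46 in mesenchymal-like cells and Rbp4 at 0.43 in endothelial-like cells. With variable genes without the ambient list, Ins1 was at 2.06 (acinar), 0.15 (macrophage) and -0.10 (mesenchymal), Ins2 at 1.87, 0.18 and -0.22, Thbs1 at -1.49 (acinar), Reg1 at 0.63 (alpha) and Spink1 at 3.65 (ductal).

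At this depth Alox15, with 0 to 7 UMIs per library, could not be compared. On simulated data the test found 21% of changes of log2 1 in macrophages and 36% in T or NK cells, against 83% in beta-like cells. Whether depth or the spread between libraries set this was not tested. The simulated genes had a more even spread than real genes can have, so these shares do not give the performance on the real libraries.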

Other observations

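The tests of the classes and genes below were fixed before; the description of sub-clusters was chosen only after the data were seen.

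Acinar-like cells, few in the knockouts, had 15 of 20 type I interferon response genes up (18 adjusted over the list alone; camera adjusted p = 2.09e-41; adjusted p = 0.102 with an estimated correlation), among them Isg15, a ubiquitin-like modifier (log2 4.66), and Bst2, the gene of tetherin (3.10). Ly6a, the gene of Sca-1, stood at 3.31 and 1.71 CPM in the controls and at 240 and 361 CPM in the knockouts (log2 6.78; adjusted p = 3.16e-05), and Thbs1, the gene of thrombospondin 1, at 5.34 and 4.80 against 215 and 168 CPM (log2 5.23). The calls of Ly6a and Thbs1 were lost with a mitochondrial limit of 10% (log2 1.81 and 1.41), with at least 1000 UMIs per cell (2.50 and 1.78) and with variable genes without the ambient list (1.38 and -1.49, the latter a turn of sign). Knockout acinar-like cells numbered 71 and 51 against 2722 and 1377, and insulin made up 23.7% and 16.04% of their UMIs against 14.5% and 10.5%. In ductal-like cells 9 of 22 type I interferon response genes rose (18 adjusted over the list alone; camera adjusted p = 6.92e-43; adjusted p = 0.184 with an estimated correlation), with Irf7 at 2.55 and Zbp1 at 3.17, and the GTPase genes Ifi47 and Igtp rose by 4.16 and 3.70. Their calls were lost without Knockout 4 (adjusted p = 0.0658 and 0.220) and without Knockout 5 (0.158 and 0.363). Knockout ductal-like cells numbered 20 and 32.

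Neutrophil-like cells of the knockouts had more Mgst2, a microsomal glutathione transferase (0 and 9.48 against 180 and 109 CPM; adjusted p = 7.63e-04), and more Anxa3 (log2 2.43; adjusted p = 0.0125), the gene of annexin A3. The Mgst2 call was lost without Knockout 5 (adjusted p = 0.12998). A pair of sub-clusters was named regulatory T cell-like. The first, with 9 of 9 markers raised and Foxp3 among its 10 leading genes, held 0% and 2.44% of the T or NK class in the controls. It held 7.69% and 10.7% in the knockouts. The other held 0%, 1.22%, 4.90% and 2.86%. It was named from 3 of 9 markers, with 1 of them among its 10 leading genes, and 4 cell cycle markers were raised in it. A sub-cluster of dividing cells, with 12 cell cycle markers, held 3.39%, 2.44%, 13.6% and 7.93%. The naming rule called it CD8 T cell-like, but from 4 of 12 markers, with 0 of them among its 10 leading genes. A CD8 T cell-like sub-cluster with Xcl1 and Gzmk held 0%, 2.44%, 11.9% and 14.6%. The class numbered 177, 82, 286 and 908 cells, and 77.4% and 36.6% of its control cells lay in the sub-cluster led by acinar transcripts, which has no name and may hide cells of these kinds (not tested). A monocyte-like sub-cluster with Chil3 and Spp1 held 18.6% and 23.6% of the macrophage class in the controls and 7.60% and 9.65% in the knockouts. Neutrophil-like cells, too, lay in different sub-clusters by group. A sub-cluster with Hcar2 held 61.8% and 56.9% of the class in the controls and 0% in each knockout. Another, with Clec4e, held 0% and 0.385% in the controls and 43.75% and 44.6% in the knockouts. No test was run on these sub-clusters.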
